A study of Homo sapiens with 35 samples.

How the data were processed

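Polyadenylated RNA was measured in 35 libraries from primary human T cells, in 6 groups. Per the labels' protocols, unwanted cells were depleted to leave T cells (negative selection), starting from blood mononuclear cells (PBMC) of healthy donors, from PBMC of patients with clear cell renal cell carcinoma, or from the patients' tumours (tumour-infiltrating T cells, TIL). The cells were stimulated with beads carrying antibodies to CD3 and CD28 and cultured for 5 days at 1% oxygen, with 2 µM belzutifan or with DMSO alone. Libraries were poly(A)-selected and stranded, and all carry the same batch number in the labels. There were 5 DMSO and 5 belzutifan libraries of healthy donors, 7 and 7 of patient PBMC, and 5 and 6 of TIL, from 12 donors in all. Healthy donor replicates 1 to 5 are 5 people, and the patients' PBMC and TIL libraries with the same replicate number come from the same donor, per the labels.

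The deposited table of gene read counts holds whole numbers for 58216 genes. Per the submitters' processing notes, FastQC, STAR 2.7.10a, Picard and RSEM 1.3.1 were used with the build GRCh38.p10, without a stated role for each. Which program counted the reads, and whether by strand, is not given in the sources used here. Among counts from 2 to 21, 72.3% were even, so both mates of a read pair appear to have been counted, and counts halved were run as an alternative. The deposited TPM table (transcript levels scaled within each library, made by the authors) sums to 1000000 in each library and was used only in alternatives. Gene coordinates are those of GENCODE 29 on GRCh38, which held 57953 of the genes. XIST, TSIX and genes of the Y chromosome, 519 genes in all, were left out of every table and test.

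Library totals ran from 21040507 to 54808537 counted reads, with a median of 43017961. The shallowest was the TIL DMSO library of replicate 6, and the next held 32509906. In no pair of libraries of a group did counts differ by sampling noise alone: the smallest chi-square per degree of freedom was 18.47. PCR duplicates are not marked by molecular identifiers in these counts, so precision was taken from the spread between cultures, not from the read totals.

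Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalization, and the quasi-likelihood test with Benjamini-Hochberg adjustment at an adjusted p under 0.05. The belzutifan effect was fitted over all 35 libraries with the culture (donor within origin) as a block and one belzutifan coefficient per origin, which gave the effect in each origin, their equal-weight mean, and the 3 differences between origins. All adjusted p-values given for single genes come from edgeR unless another tool is named. TIL replicate 4 has a belzutifan library only and adds nothing to that effect, which leaves 17 pairs. TIL and PBMC cultures of the same donors were compared within each treatment with the donor as a block (5 donors under DMSO, 6 under belzutifan). PBMC of patients and healthy donor T cells, which come from different people, were compared without a block. The block follows the donors in the labels. Deviations from the group mean correlated between the 2 libraries of a culture at r from 0.55 to 0.87 in the 17 pairs. Libraries of different donors reached at most 0.5 (in PBMC), so the values bear this pairing out. Between TIL and PBMC of a donor r was 0.15 to 0.45 under DMSO and 0.1 to 0.37 under belzutifan. Between different donors it was -0.38 to 0.37 and -0.33 to 0.32. These ranges overlap, so that pairing rests on the labels. PBMC and TIL cultures of a patient are not independent, so the mean over origins rests on 17 pairs from 12 donors.

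Levels are TMM-normalized CPM (counts scaled to a library total of 1000000) with the SD over libraries. Fold changes are edgeR log2 values with its default prior count, and the standard error (SE) is the size of the unshrunk change over the root of the F statistic. Counts of pairs refer to log2(CPM + 0.5) differences. For the size of the effect, the share of genes with a mean of at least 1 CPM was computed whose 95% interval of the unshrunk log2 fold change lay wholly within 1.5-fold or 2-fold.

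Before the data were examined, 35 gene lists were fixed (pathways, T cell states and markers of cell types), with 557 of 559 entries matched to the table. The 33 lists with at least 3 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. Named genes also followed a rule set before the data were examined: HIF1A, EPAS1, ARNT and VHL, then up to 12 higher and 12 lower genes with the largest change among those with adjusted p under 0.05, a mean of at least 5 CPM in the higher group and the same direction in at least 80% of pairs, then up to 4 members of each list with the smallest p. Where no gene passed, the 5 with the smallest p were taken. Clone-based symbols were skipped, as were antigen receptor segments and other genes that follow a person's genotype.

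The edgeR steps were tested on simulated counts made from the real means and dispersions, with 100 genes changed 1.5-fold and 100 changed 2-fold. The changed genes had a mean of at least 1 CPM, and counts were drawn independently between genes. Recovery in lower genes and false calls among correlated genes were therefore not tested. At 1.5-fold, 66 were recovered for healthy donor T cells, 82 for PBMC, 83 for TIL and 99 for the mean over origins. At 2-fold, the same comparisons recovered 93, 97, 95 and 100. The TIL against PBMC fit under DMSO recovered 35 and 67, and PBMC against healthy donors 36 and 76. False calls numbered 3 to 10 per comparison.

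Alternatives were DESeq2 1.42.0 with its own size factors, RLE normalization, no low-count filter, at least 10 reads in every library, limma-voom, limma on log2(TPM + 1), fits without the block, fits of only the groups compared, other subsets of donors, library size as a covariate, and leaving out each donor in turn. Alternatives added after the data were seen were halved counts, fits without TIL replicates 5 and 7, the belzutifan TIL comparison with only the 5 donors of the DMSO comparison, removal of GC and length trends with the block kept, and the endothelium list without EPAS1. Agreement between origins was measured as Pearson and Spearman correlations across genes, with exact enumeration of sign flips of the culture pairs. Library measures were compared between the libraries of a pair with two-sided sign-flip permutation tests, exact within an origin.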

Results

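Belzutifan blocks HIF-2α, the oxygen-regulated transcription factor encoded by EPAS1, from pairing with its partner ARNT. Its effect on RNA was compared with DMSO in 17 pairs of T cell cultures held at 1% oxygen: 5 from healthy donors, 7 from patients' PBMC and 5 from TIL. T cells of the 3 origins were then compared with each other within each treatment.

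EPAS1 itself fell under belzutifan, in all 17 pairs. Its log2 fold change, averaged over the 3 origins, was -0.77 (SE 0.0623, adjusted p = 4.16e-08), from 121 ± 125 CPM under DMSO to 71.2 ± 71.6 CPM (mean ± SD over 17 libraries each). EPAS1 lies on chromosome 2 (46293667 to 46386703, plus strand of GRCh38). Transcripts of its oxygen-labile relative HIF1A (log2 0.04, adjusted p = 0.4), of ARNT (0.04, adjusted p = 0.458) and of VHL, the ubiquitin ligase subunit that marks HIF proteins for decay (-0.009, adjusted p = 0.898), did not pass. GATM, the first enzyme of creatine synthesis, had the largest fall among the named genes (-1.34, SE 0.141, adjusted p = 3e-06, 2.44 ± 1.86 against 6.28 ± 4.53 CPM, lower in 16 of 17 pairs). ADM, which encodes the vasodilator peptide adrenomedullin, fell by 0.82 (adjusted p = 0.000607, 14 of 17 pairs). GLUL, which makes glutamine from glutamate and ammonia, fell by 0.57 (adjusted p = 0.000101, 17 of 17). The long noncoding RNA NEAT1, the scaffold of nuclear paraspeckles, rose by 0.36 (SE 0.0341, adjusted p = 8.13e-07, 933 ± 286 against 728 ± 243 CPM). IL7R, the receptor chain for the survival cytokine IL-7, rose by 0.27 (SE 0.0294, adjusted p = 3.84e-06, 254 ± 143 against 212 ± 120 CPM), and both were higher in 17 of 17 pairs.

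Genes that respond to hypoxia moved in both directions. Of 36 tested, 10 rose and 6 fell over all genes (14 and 7 adjusted over the list alone), with a median log2 fold change of 0.05 and a mean of 0.006. PDK1, which restrains entry of pyruvate into the mitochondrial citric acid cycle, rose by 0.18 (adjusted p = 0.000437) and the secreted factor STC2 by 0.20. EGLN3, an oxygen-sensing HIF hydroxylase, fell by 0.30 (adjusted p = 0.000303). The list passed camera as higher (adjusted p = 0.0384), but not with an estimated correlation (adjusted p = 0.866 with an estimated correlation). Among 20 genes known to prefer HIF-2 over HIF-1, 4 fell and 0 rose (5 and 1 adjusted over the list alone), CCND1 (cyclin D1, -0.49, adjusted p = 0.0299) among them. By origin, CCND1 had -1.53 in TIL (adjusted p = 0.00586), -0.11 in healthy donors (adjusted p = 0.927) and 0.17 in PBMC (adjusted p = 0.797). The list did not pass (camera adjusted p = 0.36). Glycolysis genes as a list did not pass either (adjusted p = 0.984): of 21, HK2 (hexokinase, 0.15, adjusted p = 0.00214) and PDK1 rose, and PKM (pyruvate kinase, -0.12, adjusted p = 0.0012) fell.

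Cell cycle genes fell together. Of 30 tested, 19 were lower and 0 higher (23 and 0 adjusted over the list alone), with a median of -0.12 and camera adjusted p = 2.16e-22. The mitotic kinases AURKA (-0.17, lower in 17 of 17 pairs) and AURKB (-0.175, adjusted p = 0.000159) and the replication helicase subunit MCM3 (-0.14, adjusted p = 0.000751) were among them. This list also passed as lower with an estimated correlation (adjusted p = 0.0329 with an estimated correlation) and with fry (adjusted p = 2.03e-05). Of 21 cholesterol synthesis genes, 10 fell and 0 rose (12 adjusted over the list alone), with a median of -0.06, led by the farnesyl diphosphate synthase FDPS (-0.16, adjusted p = 6.65e-05, 17 of 17 pairs). Unfolded protein and heat shock genes (5 of 19 lower, 10 lower and 2 higher adjusted over the list alone, median -0.07), oxidative phosphorylation genes (6 of 32 lower, 7 adjusted over the list alone, median -0.055) and activation genes (2 of 20 lower, 6 adjusted over the list alone, median -0.11) also passed camera as lower, and interferon-stimulated genes passed as higher (4 of 25 higher, 7 adjusted over the list alone, median 0.08). With an estimated correlation these 5 lists did not pass: adjusted p = 0.3 with an estimated correlation for cholesterol synthesis, 0.528 for heat shock, 0.666 for oxidative phosphorylation, and 0.624 for both the activation and the interferon list. With fry, cholesterol synthesis (adjusted p = 0.00119) and heat shock (0.0284) passed as lower. Oxidative phosphorylation (0.147), activation (0.197) and interferon genes (0.211) did not pass with fry. Beside these lists, mitochondrial transcripts took 0.878 ± 0.329% of counts under belzutifan and 1.06 ± 0.419% under DMSO, lower in 14 of 17 pairs (two-sided sign-flip permutation p = 0.00335, adjusted p = 0.0603 over 18 measures). Sign-flip tests of library measures over all 17 pairs flipped PBMC and TIL pairs of a patient as if independent, which they are not. Ribosomal protein genes took 4.87 ± 0.64% and 4.67 ± 0.388%, higher in 11 of 17 pairs (permutation p = 0.0466, adjusted p = 0.21). In TIL this share went the other way, 4.4 ± 0.488% against 4.57 ± 0.315%, lower in 4 of 5 pairs. In TIL the cholesterol list had a median of 0.014 and did not pass (12 genes positive and 9 negative, 0 called in edgeR and 0 adjusted over the list alone, camera adjusted p = 0.664). In PBMC the interferon list had a median of -0.045 and did not pass (8 positive and 17 negative, 0 called in edgeR and 3 lower adjusted over the list alone, camera adjusted p = 0.196).

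Among genes of T cell states, FOXP3, the defining transcription factor of regulatory T cells, fell by 0.39 (adjusted p = 8.8e-05, 84.3 ± 35.9 against 110 ± 47.8 CPM, 16 of 17 pairs), and TNFRSF4 (OX40) fell by 0.16 (adjusted p = 0.00858). These were 2 of 12 regulatory T cell genes (2 lower and 1 higher adjusted over the list alone). CD38, an activation-induced enzyme that consumes NAD, rose by 0.25 (adjusted p = 0.000822, 16 of 17 pairs), and the cytokine IFNG by 0.25 (adjusted p = 0.0179, 14 of 17). Of 24 effector and cytotoxic genes, 2 rose (2 adjusted over the list alone). Of 22 inhibitory receptor and exhaustion genes, 1 rose (1 adjusted over the list alone). Of 20 naive and memory genes 2 rose and 3 fell (3 and 3 adjusted over the list alone). Of 12 markers of T cells in general, 0 passed in edgeR (0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.642).

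Over all genes, 1459 of 22135 passed for the mean over origins, 632 higher and 827 lower, with a median absolute log2 fold change of 0.147, and 26 changed at least 2-fold. Of the 15671 genes with a mean of at least 1 CPM, the 95% interval lay within 1.5-fold for 96.8% and within 2-fold for 99.6%. On the deposited TPM, 985 genes were higher and 368 lower, and with GC and length trends removed 501 and 1277, so the balance of directions depended on the scaling. Without the culture block 0 genes passed in edgeR, with 1050 at an unadjusted p under 0.05.

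**Figure D1:**
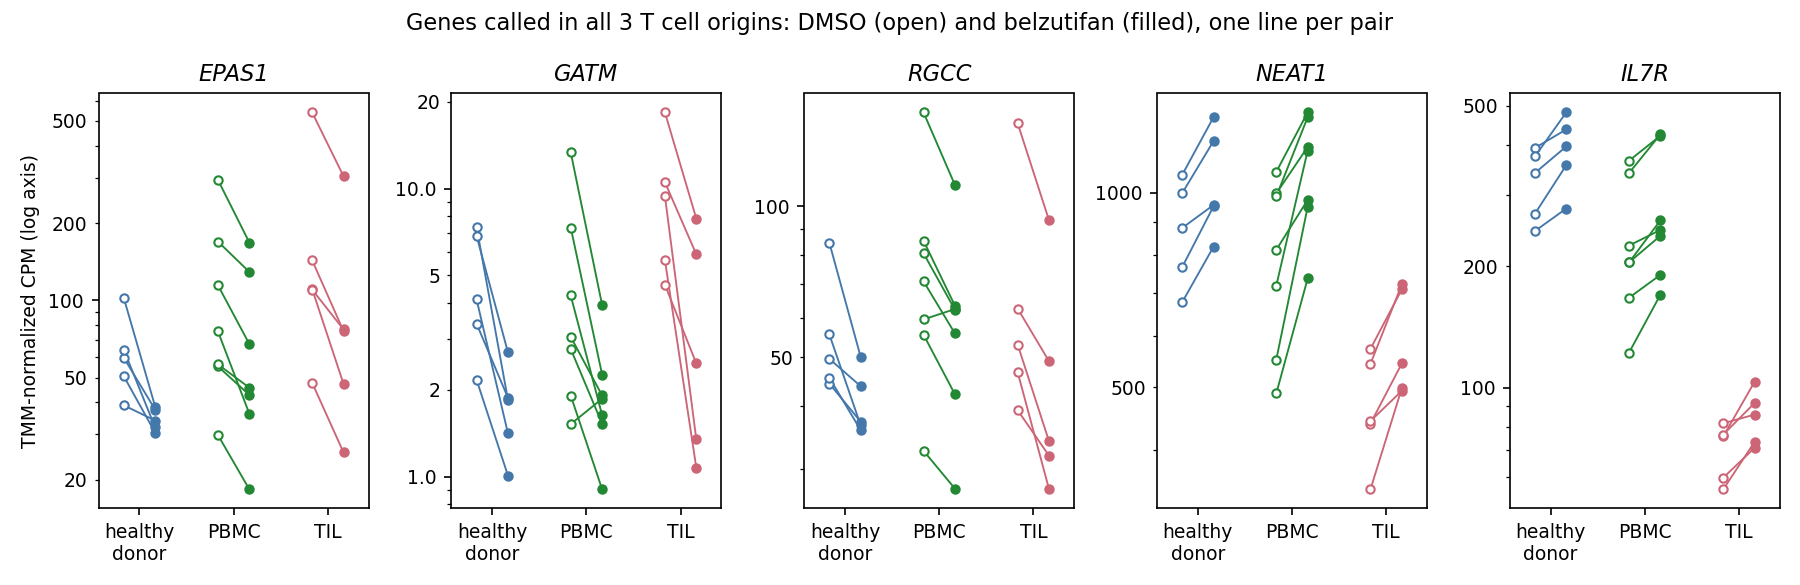
CPM (log axis) of the 5 genes called in all 3 origins, under DMSO (open) and belzutifan (filled), with one line for each of the 17 pairs. EPAS1 was lower and NEAT1 and IL7R higher under belzutifan in every pair.

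In healthy donor T cells the largest group to move was the cell cycle. All 30 cell cycle genes had a negative log2 fold change, and 17 passed (28 adjusted over the list alone), with a median of -0.19. CDC6, which loads the replication helicase, fell by 0.325 (SE 0.0551, adjusted p = 0.01), the helicase subunit MCM2 by 0.25 (SE 0.0442, adjusted p = 0.0136, 212 ± 34.3 against 251 ± 39.4 CPM), and the thymidylate synthase TYMS by 0.22 (SE 0.0404, adjusted p = 0.0136), each in 5 of 5 pairs. The list passed camera (adjusted p = 1.19e-35; adjusted p = 0.00415 with an estimated correlation). EPAS1 fell by 0.81 (SE 0.115, adjusted p = 0.00297, 34.5 ± 3.46 against 63.1 ± 23.9 CPM, n = 5 pairs), and the growth suppressor CDK2AP1 by 0.49 (SE 0.0717, adjusted p = 0.00297). Among the higher genes were BTN3A1, a butyrophilin that presents phosphoantigens to gamma-delta T cells (0.37, SE 0.0614, adjusted p = 0.01), the NK receptor chain KLRD1 (0.41, adjusted p = 0.0473) and the T cell kinase TXK (0.35, adjusted p = 0.0324).

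Of 21 cholesterol synthesis genes 2 fell, FDPS (-0.20) among them (9 adjusted over the list alone), and the chaperones HSPH1 (-0.29) and HSP90AA1 (-0.215) the 2 of 19 in the heat shock list (6 lower and 1 higher adjusted over the list alone). The camera results of these lists were lost with an estimated correlation (adjusted p = 0.424 and adjusted p = 0.567 with an estimated correlation). With fry, cholesterol synthesis passed (adjusted p = 0.0384) and heat shock did not (adjusted p = 0.23). The ATP synthase genes MT-ATP6 (-0.57, adjusted p = 0.0283, 341 ± 72.3 against 519 ± 159 CPM) and MT-ATP8 (-0.58, adjusted p = 0.04) of the mitochondrial genome fell too, and since they overlap, reads of the one cannot be assigned apart from the other with certainty. All mitochondrial transcripts together took 1.03 ± 0.294% of counts under belzutifan and 1.35 ± 0.482% under DMSO, lower in 5 of 5 pairs (exact two-sided sign-flip p = 0.0625, the smallest that 5 pairs allow, adjusted p = 0.281 over 18 measures). Interferon-stimulated genes (0 of 25 passed in edgeR, 5 adjusted over the list alone, median 0.09) and effector genes (1 of 24 higher, 2 adjusted over the list alone, median 0.15) passed camera as higher, with adjusted p = 0.567 and adjusted p = 0.718 with an estimated correlation. Gamma-delta T cell markers passed camera as higher beside them (3 of 3 positive, median 0.205, 0 called in edgeR and 1 adjusted over the list alone, adjusted p = 0.0462, adjusted p = 0.567 with an estimated correlation). Summed, these held 44.7 ± 7.63 against 38.5 ± 9.37 CPM, higher in 5 of 5 pairs (exact two-sided sign-flip p = 0.0625, adjusted p = 0.281 over 18 measures). NK cell markers were positive in 8 of 10 cases and did not pass (median 0.20, camera adjusted p = 0.144). In all, 184 genes passed, 41 higher and 143 lower. This number was 576 in DESeq2 (179 higher, 397 lower), 299 in voom (113 and 186) and 73 on the deposited TPM (30 and 43), and it was 9 without healthy donor replicate 1 and 2 without replicate 5.

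In PBMC T cells of the patients, NEAT1 showed the clearest rise (0.47, SE 0.0525, adjusted p = 3.83e-05, 1090 ± 215 against 806 ± 230 CPM, 7 of 7 pairs). EPAS1 fell by 0.63 (SE 0.0954, adjusted p = 0.00251, 72.5 ± 55 against 114 ± 92.2 CPM, 7 of 7), and so did ARG2, the mitochondrial arginase (-0.56, SE 0.0882, adjusted p = 0.00292, 26.3 ± 9.12 against 38.8 ± 12.7 CPM, 7 of 7), and TNFRSF8, the activation receptor CD30 (-0.37, SE 0.063, adjusted p = 0.00329, 96.2 ± 38.7 against 125 ± 56.9 CPM, 7 of 7). FOXP3 fell by 0.36 (adjusted p = 0.0238, 6 of 7). Higher genes included the monocarboxylate transporter family member SLC16A6 (0.525, adjusted p = 0.00801) and CD38 (0.31, adjusted p = 0.0135, 7 of 7). Of the 36 hypoxia response genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone), with STC2 (0.32) and the lipoprotein receptor VLDLR (0.37) higher and EGLN3 (-0.34) lower.

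Cholesterol synthesis led the lists in PBMC, with 5 of 21 genes lower (15 adjusted over the list alone) and a median of -0.12. They included FDPS (-0.17), DHCR7 (-0.21) and SC5D (-0.19). These were lower in 7 of 7 pairs each. Camera gave adjusted p = 3.45e-13 for the list, and adjusted p = 0.139 with an estimated correlation, while fry gave adjusted p = 0.00176. No cell cycle gene passed over all genes in edgeR, 11 passed adjusted over the list alone, and the median was -0.09 (camera adjusted p = 2.25e-10, adjusted p = 0.164 with an estimated correlation, 0.00847 with fry). The heat shock list had 2 lower members, HSPH1 and HSP90AA1 (8 lower and 1 higher adjusted over the list alone, adjusted p = 0.501 with an estimated correlation, 0.0796 with fry). In all 241 genes passed, 123 higher and 118 lower. DESeq2 called 737. GC and length correction gave 159 higher and 307 lower, and the deposited TPM 117 and 61. Without PBMC replicate 3 or 2 the number was 70 or 117.

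**Figure D2:**
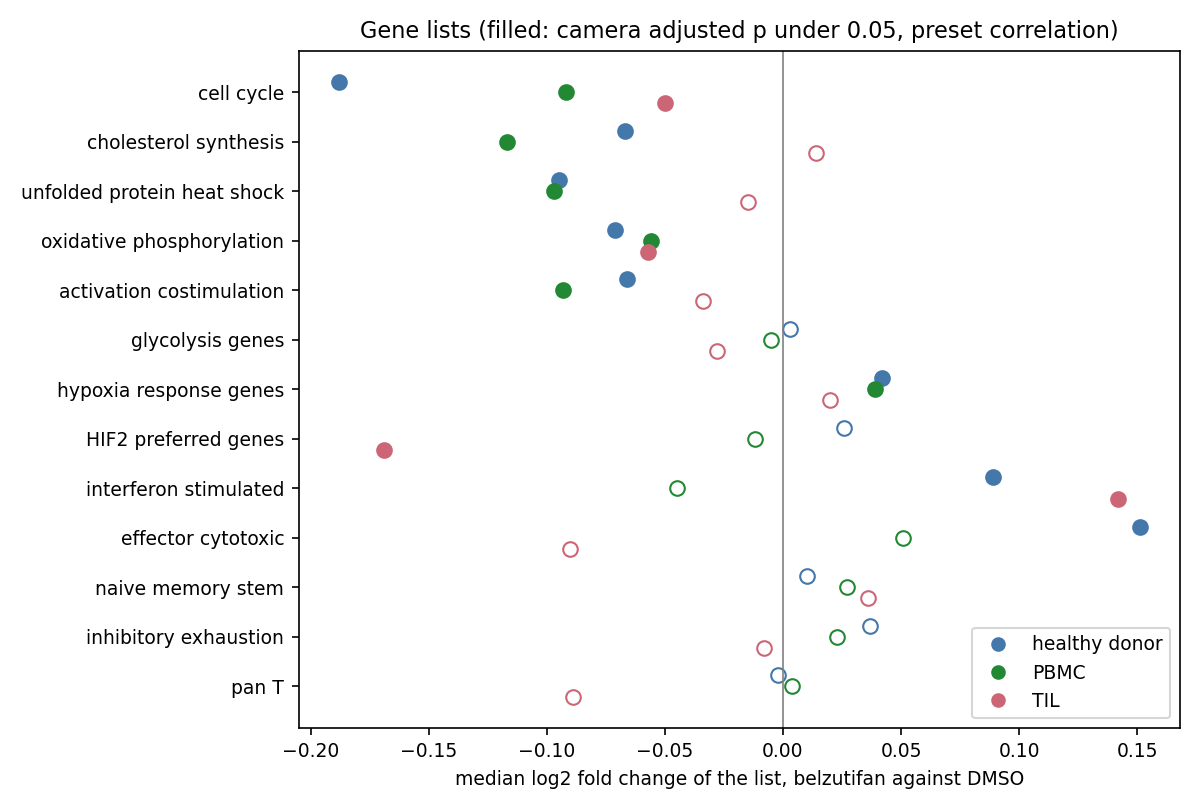
Median log2 fold change (belzutifan against DMSO) of 13 gene lists in healthy donor, PBMC and TIL cultures, with filled points where the list passed camera at its preset correlation. Cell cycle medians were -0.19, -0.09 and -0.05, and of all the points shown only the healthy donor cell cycle list also passed with an estimated correlation. In TIL the cell cycle and oxidative phosphorylation medians changed sign on the deposited TPM, to 0.009 and 0.002.

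In TIL 11 of the called genes changed at least 2-fold, 7 lower and 4 higher. EPAS1 fell by 0.88 (SE 0.112, adjusted p = 0.000554, 106 ± 113 against 190 ± 198 CPM), GATM by 1.56 (SE 0.249, adjusted p = 0.00386, 3.73 ± 3.01 against 9.72 ± 5.43 CPM), ADM by 1.53 (SE 0.262, adjusted p = 0.00824, 11.7 ± 15.3 against 35.2 ± 47.1 CPM), CCND1 by 1.53 (SE 0.254, adjusted p = 0.00586) and GLUL by 0.81 (SE 0.146, adjusted p = 0.0132, 170 ± 47.2 against 315 ± 145 CPM), each lower in 5 of 5 pairs. The creatine transporter SLC6A8 (-0.74), FOXP3 (-0.50, adjusted p = 0.0248, 60.1 ± 28.9 against 84.9 ± 39.3 CPM), TNFRSF4 (-0.33) and the costimulatory receptor CD40 (-0.59) fell as well. NEAT1 (0.34, 593 ± 113 against 469 ± 90.5 CPM), IL7R (0.28, 85.1 ± 13.4 against 70 ± 11.3 CPM), the osmotic stress factor NFAT5 (0.37, adjusted p = 0.038) and the phosphoinositide phosphatase INPP4B (0.28) rose in 5 of 5 pairs.

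Of the 20 HIF-2-preferred genes, 2 fell in TIL, ADM and CCND1 (6 lower and 1 higher adjusted over the list alone, median -0.17, camera adjusted p = 0.0267, adjusted p = 0.5 with an estimated correlation). Interferon-stimulated genes were positive in 23 of 25 cases with a median of 0.14, though 0 passed over all genes in edgeR (6 adjusted over the list alone, camera adjusted p = 7.28e-07, adjusted p = 0.473 with an estimated correlation). Markers of renal tumour and epithelium, measured beside these losses, had a median of -0.36 and did not pass (0 of 16 genes in edgeR, camera adjusted p = 0.06). Summed, they held 244.8 CPM under DMSO and 159.8 under belzutifan in TIL replicate 5, 363.3 and 325.0 in replicate 7, and 46.3 to 110 in the other libraries of all groups. Monocyte and macrophage markers passed camera as lower (median -0.235, 8 of 9 negative, 0 called in edgeR and 1 adjusted over the list alone, adjusted p = 0.031, adjusted p = 0.473 with an estimated correlation). Their summed level was 55.7 ± 14.7 against 74.6 ± 30.6 CPM, lower in 5 of 5 pairs (exact two-sided sign-flip p = 0.0625, adjusted p = 0.375 over 18 measures). The largest drops from DMSO to belzutifan were in replicates 6 (84.49 to 44.06 CPM) and 7 (124 to 81.43). Replicates 1 (49.85 to 49.56), 3 (55.96 to 50.72) and 5 (58.72 to 52.65) moved less. Gamma-delta T cell markers passed camera as lower too (3 of 3 negative, median -0.26, 0 called in edgeR and 2 adjusted over the list alone, adjusted p = 0.0325, adjusted p = 0.473 with an estimated correlation). In all 51 genes passed, 23 higher and 28 lower. DESeq2 called 134 higher and 80 lower, voom 62 and 144 and the deposited TPM 9 and 3. Without TIL replicates 5 and 7 EPAS1 (-0.89) and GATM (-1.94) passed alone, at adjusted p = 0.0494 each, while 51 of the 51 genes, which were chosen on these pairs, kept their direction. Some falls shrank: GLUL went from -0.81 to -0.43, SLC6A8 from -0.74 to -0.48 and FSCN1 from -0.60 to -0.39. Others held or grew: SYNPO went from -1.113 to -1.109, CCND1 from -1.53 to -1.85 and ADTRP from -0.74 to -0.84.

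**Figure D3:**
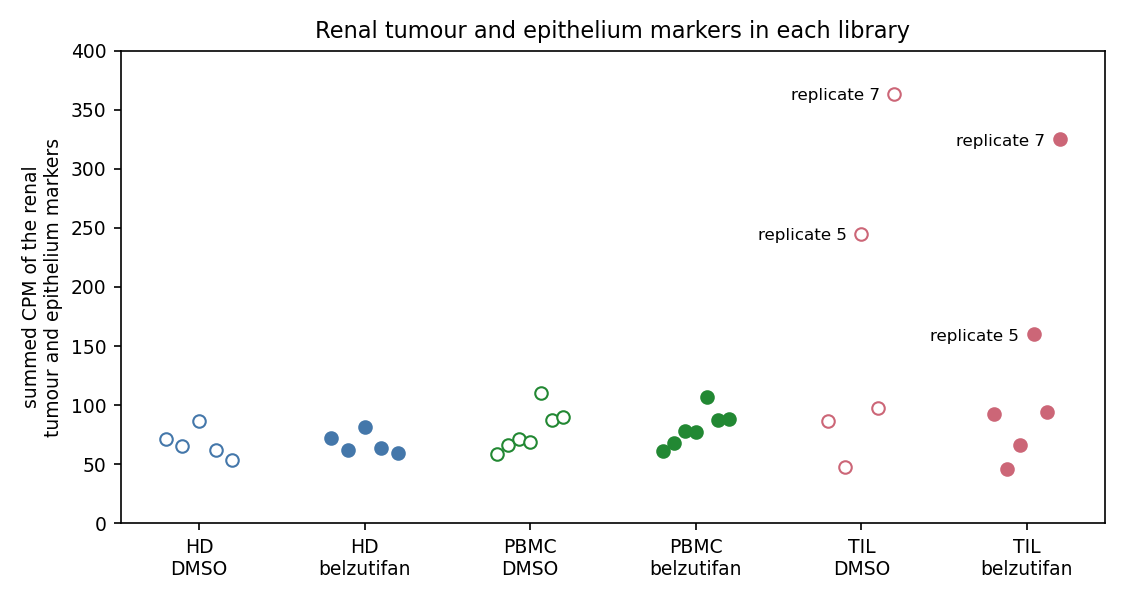
Summed CPM of 18 renal tumour and epithelium markers in each of the 35 libraries, one point per library, under DMSO (open) and belzutifan (filled). The 4 libraries of TIL replicates 5 and 7 reach 159.8 to 363.3 CPM, above all others.

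EPAS1, GATM, RGCC, NEAT1 and IL7R were the 5 genes that passed in each of the 3 origins. RGCC, a regulator of the cell cycle named here after its values were seen, had log2 fold changes of -0.43 in healthy donors, -0.31 in PBMC and -0.54 in TIL. GATM had -1.38, -1.08 and -1.56, and IL7R 0.27, 0.27 and 0.28. All 184 genes called in healthy donors had the same direction in PBMC, and 66 were called in both, with 0.99 expected by chance. In TIL 129 of those 184 genes and 155 of the 241 PBMC genes had the same direction. Of the 51 TIL genes, 42 had the same direction in healthy donors and 39 in PBMC, with 6 and 10 called in both (0.22 and 0.28 expected). Across genes, which are not independent replicates, the effects in healthy donors and PBMC correlated at Pearson r = 0.218 and Spearman rho = 0.325 (exact sign-flip permutation p = 0.000977 for each, the smallest possible, adjusted p = 0.00293 over 3 relations). TIL correlated with healthy donors at r = 0.156 (permutation p = 0.0156, adjusted p = 0.0156) and rho = 0.151 (p = 0.0547, adjusted p = 0.082), and with PBMC at r = 0.122 (permutation p = 0.00781, adjusted p = 0.0117) and rho = 0.125 (p = 0.0869, adjusted p = 0.0869). For TIL with PBMC the pairs were flipped as if independent, although the paired TIL donors also supplied PBMC, so responses shared within a donor were not allowed for. Among genes of at least 10 CPM the relation of healthy donors with PBMC was r = 0.685. Those of TIL were r = 0.267 with healthy donors and 0.207 with PBMC, larger than over all genes, and did not pass (adjusted p = 0.255 each).

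The effect differed between TIL and PBMC for 7 genes in edgeR and for 141 in DESeq2. Without PBMC replicate 1 edgeR called 90, and without PBMC replicate 2, 3 or 4 or TIL replicate 5, 6 or 7 it called 0 (2129, 1848, 1922, 1848, 1871 and 1963 at an unadjusted p under 0.05). Among the 7, SLC38A2, an amino acid transporter, had 0.243 in TIL and -0.179 in PBMC (difference 0.42, adjusted p = 0.0208), the taurine transporter SLC6A6 had 0.17 and -0.32 (0.49, adjusted p = 0.0306), the fatty acid desaturase FADS1 0.0924 and -0.23 (0.32, adjusted p = 0.0208), and HERC5, the ligase for the interferon-induced modifier ISG15, 0.255 and -0.147 (0.40, adjusted p = 0.0335). Between TIL and healthy donors 2 genes differed (83 in DESeq2), CDK2AP1 (0.127 against -0.491, adjusted p = 0.0238) and the clone-based gene AC068768.1, and these 9 genes were named after their values were seen. Without healthy donor replicate 1, 4 or 5, or TIL replicate 1 or 6, 0 genes differed between TIL and healthy donors in edgeR (1584, 1451, 1664, 1986 and 1673 at an unadjusted p under 0.05). Between PBMC and healthy donors 0 genes differed in edgeR, with 557 at an unadjusted p under 0.05, and 0 in DESeq2 (638 at an unadjusted p under 0.05) and voom. The effects on cell cycle genes were above those in healthy donors for 30 of 30 genes in PBMC and for 30 of 30 in TIL (camera adjusted p = 3.88e-16 and 1.9e-13, adjusted p = 0.114 and 0.187 with an estimated correlation, 0.127 and 0.0365 with fry). In TIL the effects on gamma-delta T cell markers (3 of 3, median difference -0.50, 2 adjusted over the list alone, camera adjusted p = 0.000714) and on monocyte and macrophage markers (9 of 9, -0.48, 1 adjusted over the list alone, adjusted p = 0.0161) lay below those in healthy donors. These had adjusted p = 0.187 and adjusted p = 0.269 with an estimated correlation. For interferon-stimulated genes the effect in PBMC lay below that in healthy donors in 25 of 25 cases (1 adjusted over the list alone). Camera gave adjusted p = 7.98e-12, and adjusted p = 0.196 with an estimated correlation. In TIL it lay above that in PBMC in 22 of 25 cases (9 adjusted over the list alone, adjusted p = 1.09e-07). For cholesterol synthesis genes it lay above in 19 of 21 (7 adjusted over the list alone, adjusted p = 6.54e-06). Both of these had adjusted p = 0.688 with an estimated correlation. With only the 5 donors that have all 4 libraries, 0 genes differed between TIL and PBMC in edgeR, with 1504 at an unadjusted p under 0.05.

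Naive and memory genes were lower in TIL than in PBMC T cells of the same donors under DMSO. Of 20 tested, 9 fell (13 adjusted over the list alone), with a median of -0.85 (camera adjusted p = 2.55e-10, adjusted p = 0.106 with an estimated correlation, 0.00553 with fry). The transcription factors TCF7 (-2.74, SE 0.423, adjusted p = 0.0205, 24.8 ± 19.7 against 160 ± 98.3 CPM) and LEF1 (-1.82, SE 0.125, adjusted p = 0.00234, 48.3 ± 18.8 against 165 ± 36.3 CPM) keep T cells in naive and memory states, and both were lower in 5 of 5 donors. Higher in TIL were CCL5, a chemokine of effector T cells (1.08, adjusted p = 0.0148, 854 ± 434 against 423 ± 254 CPM), TOX, a transcription factor of exhausted T cells (1.03, adjusted p = 0.0258), the residency integrin ITGA1 (1.92, adjusted p = 0.0306) and the B cell attractant CXCL13 (3.22, adjusted p = 0.0205, 3.01 ± 3.74 against 0.204 ± 0.116 CPM). EPAS1 did not pass (0.64, SE 0.467, adjusted p = 0.47, higher in 4 of 5).

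General T cell markers were also lower in TIL, 3 of 12 over all genes and 10 adjusted over the list alone (median -0.41), with LCK (-0.515) and ZAP70 (-0.50), kinases of the T cell receptor pathway, among them. The list had camera adjusted p = 1.78e-07, adjusted p = 0.485 with an estimated correlation and 0.0648 with fry. Renal tumour and epithelium markers moved the other way in the same comparison, positive in 13 of 13 genes with a median of 1.23 (0 passed in edgeR, 2 adjusted over the list alone, camera adjusted p = 0.00142, adjusted p = 0.573 with an estimated correlation). In all 610 of 19637 genes passed, 217 higher and 393 lower, and 269 at least 2-fold. Without the donor block the number was 226. Without TIL replicates 5 and 7 it was 417 (236 of them among the 610), and leaving out patient 6, 5 or 1 gave 67, 71 or 156.

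**Figure D4:**
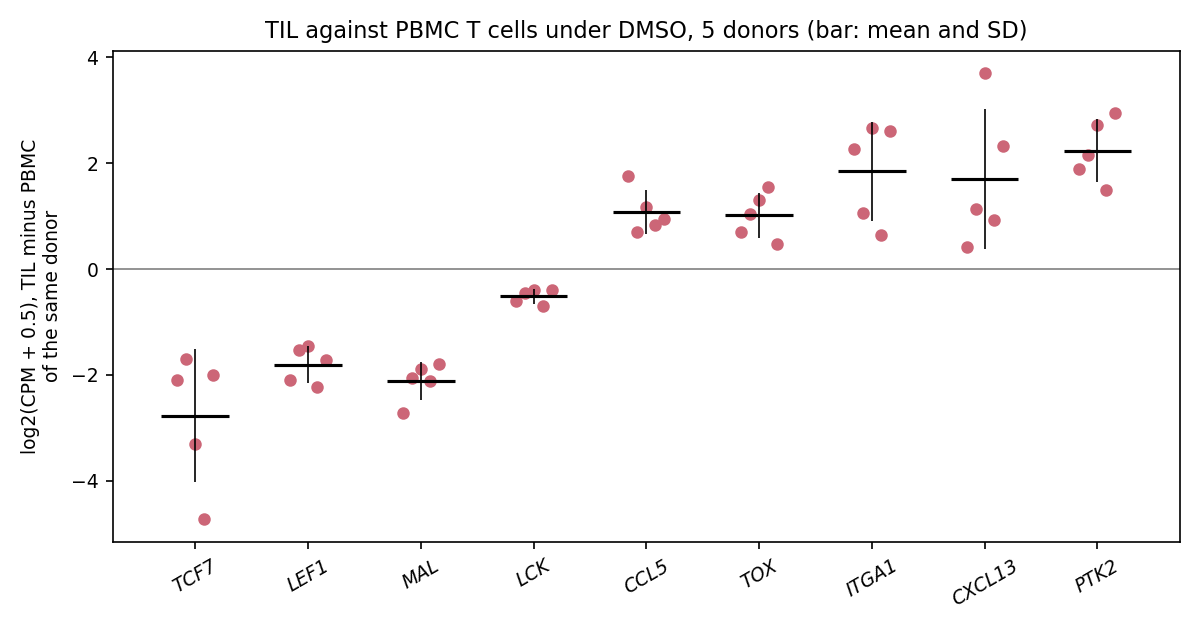
Difference in log2(CPM + 0.5) between TIL and PBMC of the same donor under DMSO for 9 named genes, one point per donor (n = 5), with the mean (horizontal bar) and SD (vertical line). All 5 donors lie below 0 for TCF7, LEF1, MAL and LCK and above 0 for CCL5, TOX, ITGA1, CXCL13 and PTK2.

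Under belzutifan the comparison of TIL with PBMC, over 6 donors, gave 2614 of 19232 genes, 1199 higher and 1415 lower. TCF7 (-3.26, SE 0.655, adjusted p = 0.02) was again lower in TIL, and TOX (1.42, SE 0.238, adjusted p = 0.0121), ITGA1 (2.59, SE 0.352, adjusted p = 0.00838) and ENTPD1, the ectonucleotidase CD39 (1.51, adjusted p = 0.0241), higher. FOXP3 (-0.92, adjusted p = 0.0488, 5 of 6 donors), CTLA4 (-0.775) and CD40LG (-1.25) were lower. Of 17 interferon-gamma and MHC class II genes, 6 were higher, with HLA-DPA1 (0.645) and its regulator CIITA (0.58), and 3 lower (9 and 5 adjusted over the list alone). Naive and memory genes (9 of 20 lower, 13 adjusted over the list alone) and T cell markers (7 of 12 lower, 11 adjusted over the list alone) passed camera, each with adjusted p = 0.731 with an estimated correlation and 0.0398 with fry. Markers of NK cells (median 1.09, camera adjusted p = 0.238), B cells (-1.06, adjusted p = 0.0613) and renal tumour and epithelium (0.52, adjusted p = 0.238) did not pass. TIL replicate 4, which enters under belzutifan alone, held 758 CPM of NK cell markers where the next TIL belzutifan library held 139. Its IL7R was 6.26 CPM, and 71.0 to 103.5 in the others. EPAS1 did not pass (0.12, SE 0.519, adjusted p = 0.903). With the 5 donors of the DMSO comparison 2249 genes passed, without TIL replicates 5 and 7 1585, and leaving out patient 5, 6, 3 or 1 gave 461, 616, 783 or 1460. On the deposited TPM 1645 genes were higher and 1284 lower.

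PBMC T cells of patients and T cells of healthy donors, which come from different people, differed in 0 of 19967 genes under DMSO in edgeR, with 1515 at an unadjusted p under 0.05, 66 in DESeq2 and 0 in voom. Under belzutifan 2 genes fell in patients: CHI3L2, a secreted chitinase-like protein (-1.60, SE 0.191, adjusted p = 0.0081, 8.25 ± 2.49 against 25.0 ± 3.64 CPM), and CEP128, a centriole protein (-0.81, SE 0.0963, adjusted p = 0.0081, 25.0 ± 2.57 against 43.7 ± 5.29 CPM). CHI3L2 had -1.37 under DMSO (adjusted p = 0.123). Activation genes were positive in 20 of 20 cases under DMSO (median 0.505, 0 over all genes in edgeR and 11 adjusted over the list alone, camera adjusted p = 6.5e-13), as were immediate early genes in 14 of 14 (median 0.44, 5 adjusted over the list alone, 3.5e-07). Both lists had adjusted p = 0.144 with an estimated correlation. B cell markers moved the other way in the same comparison, negative in 8 of 8 cases (median -0.55, 0 called in edgeR and 1 adjusted over the list alone, camera adjusted p = 0.0055, adjusted p = 0.435 with an estimated correlation). Under belzutifan they were negative in 8 of 8 cases as well (median -0.44, 0 adjusted over the list alone, camera adjusted p = 0.045, adjusted p = 0.572 with an estimated correlation). EPAS1 had 0.85 under DMSO (adjusted p = 0.675) and 1.07 under belzutifan (adjusted p = 0.48).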

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

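The tests of residual tumour cells, of nuclear RNA, and of both explanations for lower T cell genes in TIL were chosen after the results were seen, and the other tests of this part before.

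The first pattern is the 28 genes lower with belzutifan in TIL (median log2 fold change -0.597), GATM, ADM and CCND1 among them. Residual tumour cells, a candidate source of such RNA in TIL, are absent from healthy donor blood, yet the same 28 genes had a median of -0.226 in healthy donor T cells, where 95% of random gene sets matched in expression had medians of -0.055 to 0.048, with 22 negative and 4 called lower. That argues against tumour cells as the whole cause, while CCND1 (-0.11 in healthy donors), ADTRP (0.07) and CD40 (0.03) stay open, as does any added loss in TIL replicates 5 and 7, whose renal markers were high. Without those replicates CCND1 went from -1.53 to -1.85 and ADTRP from -0.74 to -0.84, so their falls were no smaller without these cultures. Both genes were chosen on a fit that held the remaining pairs too, so this is not independent support. CD40 went from -0.59 to -0.43, and none of these genes passed in that fit. Without the shallow pair of replicate 6 the median of the 28 genes was -0.638 and 28 of 28 stayed negative, so the falls did not shrink. The genes were chosen on a fit that held the remaining pairs too, so their kept direction says little by itself. In that fit 23 genes passed in TIL, 16 of them lower, against 51 and 28 with replicate 6. Belzutifan acting on T cells themselves remains a hypothesis, and monocyte and macrophage markers, lower in 5 of 5 TIL pairs (55.7 ± 14.7 against 74.6 ± 30.6 CPM), leave a change in other cells of the cultures open. The drop was uneven: largest in replicates 6, with the shallow DMSO library, and 7, and small in replicates 1, 3 and 5.

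A second pattern is the 123 genes higher with belzutifan in PBMC T cells, such as NEAT1 and IL7R. With GC and length trends removed, 96.1% of the genes that limma called higher (122 of 127) stayed called and their median log2 fold change went from 0.317 to 0.3, although the 123 genes had a median GC content of 51.4% and length of 4418 bases against 48.7% and 2618 among all tested. With libraries thinned to the total of the shallowest PBMC library, 93.5% of the 123 (115) stayed called, so neither trend nor depth was the whole cause. Of the 123, 22.8% (28) were not protein coding, beyond random sets matched in expression (median 13%, upper bound 18.7%) and the lower genes (3.39%), which is what a larger share of nuclear or unspliced RNA under belzutifan would give. A shift of RNA between libraries may therefore contribute, a change in transcription of noncoding genes would look alike, and the gene counts do not separate intron reads.

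The last pattern is the lower T cell genes in TIL than in PBMC of the same donors under DMSO. Tumour cells in the cultures with renal markers could lower them, but TIL replicates 1, 3 and 6, without a raised sum of renal markers, had pan T medians of -0.305 or lower, which argues against that as the whole cause. Single markers were above healthy donors there, such as CDH2 in TIL DMSO replicate 3 (6.25 CPM against at most 0.65) and ANGPTL4 in replicate 6 (5.87 against 3.68). In patients' PBMC T cells CDH2 reached 2.31 CPM and ANGPTL4 7.32, so the ANGPTL4 value of replicate 6 was not particular to TIL. Among the renal markers, NDUFA4L2 reached 27.5 CPM in TIL DMSO replicate 5 and 106 in replicate 7, against at most 2.58 in the other TIL DMSO libraries and 5.37 in healthy donors. Of the 18 markers, 7 had at least 1 CPM in healthy donor T cells, with GGT1 highest at 47.8. Others were hardly detected there: NNMT had at most 0.0947 CPM, against 22.7 and 21.2 in TIL DMSO replicates 5 and 7. Not every marker was raised: SLC17A3 had 0.147 CPM in TIL DMSO replicate 5 and up to 0.733 in healthy donors. The negative selection was meant to leave T cells, and whether it removed every tumour cell cannot be told from these counts. Dilution by other cells that lack T cell genes cannot be told apart from a lower expression per cell: naive and memory genes lay below the pan T genes by -0.222 to -0.596 in the 5 donors, and the smallest of these gaps is too close to 0 to exclude dilution.

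Other splits of the libraries, counted with limma, bore on each number of genes. Swapping the labels within pairs (the treatments of a culture, or the origins of a donor for TIL against PBMC) gave as many genes as the real grouping in 1 of 64 cases in PBMC (the real one, 257 genes against at most 32), 1 of 100 for the mean over origins (1528 against 265) and 1 of 32 for TIL against PBMC under belzutifan (2879 against 0). These shares argue against chance there, and each is the smallest that its swaps allow. For the mean, PBMC and TIL cultures of a patient were swapped separately, although they are not independent. With 16 such swaps each, healthy donors (181 against 1), TIL (80 against 22) and TIL against PBMC under DMSO (773 against 1) had too few for a share under 0.05. Free regrouping breaks the pairs that these fits rest on, so its counts are given without a verdict on chance: as many genes came in 1 of 100 splits for healthy donors (181 against 20) and for the mean (1528 against 81), 2 of 100 for PBMC (257 against 268), 9 of 100 for TIL (80 against 272), 3 of 100 for TIL against PBMC under DMSO (773 against 1041) and 2 of 100 under belzutifan (2879 against 3564). No free split as large as the real one parted all pairs: the highest parted 3 pairs in PBMC, 1 in TIL, 3 in TIL against PBMC under DMSO and 4 under belzutifan. Patients and healthy donors, who are unpaired, gave 2 genes under belzutifan, where 2 of 100 splits, the real one included, gave as many. That share is under 0.05, but a random split gave more genes (5) than the real one, so chance is not excluded. For the difference of TIL and PBMC 2 of 100 splits gave as many (2 against 2), but these splits ignore that 5 patients supply both origins, and with only those 5 donors edgeR called 0 genes (1504 at an unadjusted p under 0.05), so chance stays open there. Where the real number was 0, for patients against healthy donors under DMSO (0 against 212) and for the differences of PBMC (0 against 1) and TIL (0 against 2) from healthy donors, all 100 of 100 splits gave as many by construction, which says nothing of chance.

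Single libraries stood far from the others of their group in 18 of 245 groups tested, where about 12.2 would do so by chance. Chance flags about 1 in 20 groups. Summed marker levels stood apart, in CPM with the nearest library in parentheses, for monocytes and macrophages in healthy donor belzutifan replicate 4 (65.4, 50.4), fibroblasts and pericytes in PBMC replicate 7 under belzutifan (76.2, 54.6) and DMSO (101, 63.8), NK cells in PBMC replicate 1 under belzutifan (193, 50.4) and DMSO (294, 42) and in TIL belzutifan replicate 4 (758, 139), plasma cells in that TIL library (310, 190), dendritic cells in TIL belzutifan replicate 5 (39.6, 17.3) and gamma-delta T cells in TIL DMSO replicate 3 (215, 76). The 10 most abundant genes took 5.23% of counts in healthy donor DMSO replicate 4 and at least 5.69% in the others. Belzutifan log2 differences stood apart in healthy donors for FAM210B in replicate 1 (0.751, nearest 0.373) and UVSSA in replicate 4 (0.0609, nearest 0.383), and in TIL for CD40 in replicate 5 (-0.996, nearest -0.515). Differences of TIL from PBMC stood apart under DMSO for EPAS1 in replicate 3 (-1.82, nearest 0.873), and under belzutifan for VHL in replicate 4 (0.0831, nearest -0.271), MGST1 in replicate 7 (3.94, nearest 1.12), IFI27 in replicate 5 (4.15, nearest 1.56) and LINC00565 in replicate 4 (-4.41, nearest -2.7).

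The belzutifan effect differed between TIL and PBMC in an edgeR test of the difference for WBP1 (-0.457, -0.274 in TIL and 0.183 in PBMC), SLC6A6 (0.489, 0.166 and -0.323), HERC5 (0.402, 0.255 and -0.147), FADS1 (0.322, 0.0924 and -0.23), VWA5A (-0.545, -0.273 and 0.272), SLC38A2 (0.422, 0.243 and -0.179) and PPDPF (-0.462, -0.273 and 0.189), at adjusted p from 0.0208 to 0.0335. Between TIL and healthy donors it differed for AC068768.1 (0.726, 0.226 and -0.5) and CDK2AP1 (0.618, 0.127 and -0.491), at adjusted p = 0.0238.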

How the results depend on the processing

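Fits with halved counts, fits without TIL replicates 5 and 7, GC and length correction and the endothelium list without EPAS1 were chosen after the data were seen. Refits followed HIF1A, EPAS1, ARNT and VHL and the genes named for the largest changes or the smallest p over all genes. Genes named only as list members, and single genes of the differences between origins, were not followed. Each followed gene that had passed kept its direction: of 2494 refits of 146 calls (a gene called in more than 1 comparison counts in each), 1974 stayed past the threshold, 520 fell short (286 of them with a donor left out) and 0 reversed, and 17 calls passed in every refit. Among the settings that kept every donor, the fits without the block lost 112 of 144 calls and those on the deposited TPM 51 of 146. EPAS1 lost its belzutifan call only in the fits without the block. Of 599 refits where a followed gene had not passed, 14 passed. No scaling moved the median of all genes by over 0.1 on the log2 scale. The cause of these shifts was not tested. At these spreads and depths the test on simulated data recovered 66 of 100 genes of at least 1 CPM changed 1.5-fold in healthy donors, so smaller changes there were often out of reach.

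Numbers of called genes moved over 1.5 times as follows. DESeq2 gave 576 in healthy donors, 737 in PBMC, 214 in TIL, 141 for TIL minus PBMC, 83 for TIL minus healthy donors, 2154 and 4275 for TIL against PBMC under DMSO and belzutifan, and 66 and 113 for patients against healthy donors. Without the low-count filter the same results, the last under belzutifan, were 470, 596, 508, 290, 186, 1539 (DMSO) and 7, with 24 for PBMC minus healthy donors. Voom gave 299, 394, 206, 23 and 16 for the first 5. The deposited TPM gave 73 in healthy donors and 12 in TIL. With at least 10 reads in every library PBMC had 384, TIL minus PBMC 11 and TIL minus healthy donors 8. The last was also 4 with RLE, 5 with halved counts and 4 with only the groups compared, a setting that gave 362 in healthy donors and 1 for TIL minus PBMC. With only the 5 PBMC donors that have a TIL pair, PBMC had 38 and TIL minus PBMC 0 in edgeR (1504 at an unadjusted p under 0.05). GC and length correction gave 466 in PBMC. Without TIL replicates 5 and 7, TIL had 2, edgeR gave 0 for TIL minus PBMC (1552 at an unadjusted p under 0.05) and 0 for TIL minus healthy donors (1608), and TIL against PBMC under belzutifan 1585. By less than 1.5 times the same setting moved TIL against PBMC under DMSO to 417 and the mean over origins to 1109.

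Without the paired block edgeR called 0 genes in healthy donors (203 at an unadjusted p under 0.05), 0 in PBMC (388), 0 in TIL (1079) and 0 for the mean (1050), and 226 for TIL against PBMC under DMSO, while under belzutifan it called 2594. With camera 89 list results passed, with an estimated correlation 2, and with fry 19, not all of them among the 89. The agreement of healthy donors with TIL was 0.267 (adjusted p = 0.255) at 10 CPM or more and 0.163 (0.0664) on TPM, and that of PBMC with TIL 0.207 (0.255) at 10 CPM or more. The endothelium list, which holds EPAS1, had a median of -0.026 in healthy donors and 0.07 without EPAS1, and its PBMC call (camera adjusted p = 0.0138) ended without EPAS1 (0.307). Summed without EPAS1, these markers were still lower in 7 of 7 PBMC pairs (55.2 ± 16.9 against 63.4 ± 20.8 CPM). The exact two-sided sign-flip p was 0.0156 (adjusted p = 0.281 over 18 measures). They were lower in 14 of 17 pairs of all origins (permutation p = 0.0105, adjusted p = 0.0945), with PBMC and TIL pairs of a patient flipped as if independent.

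Leaving out one donor or pair gave 2 (without replicate 5) to 96 genes in healthy donors (9 without replicate 1, 94 without 3, 79 without 4), 70 (without 3) to 323 in PBMC (117 without 2, 143 without 4, 149 without 6, 146 without 7), 11 (without 5) to 59 in TIL (23 without 6, 19 without 7), and 835 (without patient 3) to 1574 for the mean (946 and 898 without healthy donors 2 and 5). It gave 0 to 90 for TIL minus PBMC (90 without PBMC replicate 1, 37 without TIL replicate 3, 0 without PBMC replicate 2, 3 or 4 or TIL replicate 5, 6 or 7), 0 to 0 for PBMC minus healthy donors and 0 to 12 for TIL minus healthy donors. TIL against PBMC ranged from 67 (without patient 6) to 1191 (without 7) under DMSO, with 156 without 1 and 71 without 5, and from 461 (without 5) to 3173 under belzutifan, with 1460, 783 and 616 without 1, 3 and 6. Patients against healthy donors ranged from 0 to 1 under DMSO and from 2 to 12 under belzutifan, where 12 came without healthy donor 3 and 9 without PBMC replicate 1.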

Other observations

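The lists, gene choices and comparisons of this part were fixed before the data were examined, and the TIL library without a partner was singled out after its values were seen.

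Cholesterol synthesis and ATF4 stress genes were also compared between TIL and PBMC of the same donors under DMSO. Of 21 cholesterol synthesis genes, 2 fell (12 adjusted over the list alone, median -0.25): LSS, the lanosterol synthase (-0.61, SE 0.0838, adjusted p = 0.0136, 196 ± 32.2 against 297 ± 32.9 CPM), and SC5D (-0.36, SE 0.0706, adjusted p = 0.0413), each in 5 of 5 donors. ASNS, the asparagine synthetase, rose by 0.66 (SE 0.0901, adjusted p = 0.0134, 109 ± 13 against 69.3 ± 14.1 CPM), 1 of 20 genes of the ATF4 stress response to pass (6 adjusted over the list alone, median 0.39). Both lists passed camera (adjusted p = 5.01e-08 and 0.000261), but not with an estimated correlation (adjusted p = 0.485 and adjusted p = 0.573 with an estimated correlation). With fry, cholesterol synthesis passed (adjusted p = 0.0345) and the ATF4 list did not (adjusted p = 0.316). EGLN3, the HIF hydroxylase, was lower in TIL by -1.40 (SE 0.257, adjusted p = 0.035, 29.8 ± 9.85 against 79.4 ± 29.1 CPM), as were the cytokine receptors IL12RB2 (-0.69, adjusted p = 0.0412) and IL18R1 (-0.55, adjusted p = 0.0313).

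The same ATF4 list was positive in 20 of 20 genes in PBMC of patients against healthy donors under belzutifan (median 0.44, 0 of 20 over all genes in edgeR, 10 adjusted over the list alone, camera adjusted p = 1.19e-09, adjusted p = 0.536 with an estimated correlation). Heat shock and unfolded protein genes were positive in 19 of 19 under each treatment (medians 0.30 and 0.27, 2 and 0 adjusted over the list alone), with adjusted p = 0.435 and 0.536 with an estimated correlation. Among genes of T cell states, belzutifan averaged over origins lowered CCR7, the lymph node homing receptor (-0.14, SE 0.0286, adjusted p = 0.00346, 15 of 17 pairs), and raised the cytokine IL21 (0.38, SE 0.0995, adjusted p = 0.0202, 13 of 17 pairs). The TIL belzutifan library of replicate 4, which has no DMSO partner and adds nothing to the belzutifan effect, held 6.26 CPM of IL7R, where the other 5 TIL belzutifan libraries held 71.0 to 103.5.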
